A study of Homo sapiens with 6 samples.

How the data were processed

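RNA-seq was done on MDA-MB-231 cells, an established triple-negative breast cancer line, 48 h after transfection with 20 nM siRNA. Of the 6 libraries, 3 came from cells given a negative control siRNA (si-Control, in the labels the Ambion product AM4611) and 3 from cells given 1 siRNA against NRDE2 (si-NRDE2-2). Per the labels' protocols, total RNA was isolated with the mirVana kit and poly(A)-selected stranded libraries were made with the TruSeq Stranded mRNA kit. Groups and replicate numbers were taken from the sample titles, and the columns of the table were matched to samples through the labels' descriptions. Nothing says whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

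The deposited table holds FPKM values (fragments scaled by transcript length and library depth) that the authors computed per gene and library. Its name speaks of counts and holds the string Cuff, which points to a tool of the Cufflinks family, but the values carry decimals and sum to between 448986 and 486271 per library. Per the submitters' processing notes, STAR 2.5.1b, DESeq2 1.10.1 and the hg19 build were used, with no role given for either tool. Apart from that string, the program that made the FPKM values is not given in the sources used here, nor are its annotation and strand setting. The test planned before the data were examined was a count test, with limma on log2 values as the stated replacement if the values were not counts, and that replacement was used. The table has 25365 rows, of which 5825 were at 0 in all 6 libraries. RPS18, a ribosomal protein gene used by every cell, was listed at 0 throughout, so a 0 here can be a failed estimate. No mitochondrially encoded transcript of the fixed list matched a row. In addition, 28 rows carried gene names turned into dates by a spreadsheet and are not named in the text. Another 4 columns, with values in only 3 rows, were not used. Symbols were matched to RefSeq symbols or synonyms for 24050 rows and to GENCODE release 29 for 23501 rows. That annotation is of GRCh38 and the table of hg19, so no coordinates are given. It served only for names, transcript length, GC content, introns and untranslated regions, with 1 transcript per gene.

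Library depth was estimated from the steps between low values, since 1 fragment is worth a fixed FPKM for a given gene. Among 1867 genes with a mean of at most 0.05 FPKM, 764 (40.9%) had values in whole multiples of their smallest within a tolerance of 0.02. The estimated depth was 53600000, 56100000 and 49200000 fragments for si-Control replicates 1, 2 and 3 and 50800000, 51900000 and 40800000 for si-NRDE2-2 replicates 1, 2 and 3. The absolute scale rests on 252 genes, with quartiles of 46500000 and 56900000 for si-Control replicate 1. At this depth a transcript of 2 kb at 1 FPKM had about 81.6 fragments in the shallowest library.

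The values were used as deposited, with no further scaling. Genes with at least 1 FPKM in at least 3 libraries were tested, after 159 rows of small RNAs, whose length makes FPKM unstable, were left out. This left 11789 genes. log2(FPKM + 0.1) was fitted with limma 3.58.1 in R 4.3.3 with a trended and robust prior variance, the 2 groups as the only term, and Benjamini-Hochberg adjustment. An adjusted p under 0.05 was called. The filter, the pseudocount and the removal of small RNAs were set after a first exploratory fit to these values. A log2 fold change is on the log2(FPKM + 0.1) scale, which understates the change of low genes, and its error is the standard error (SE), whereas a fold or ratio is that of the group means in FPKM. Named genes followed a rule fixed before the data were examined. NRDE2 and CEP131 were always named. Then came the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with a mean of at least 5 in FPKM (CPM in the rule as written) and no overlap between the groups. Pseudogenes, clone-based names, antisense and readthrough loci were left out of these. Up to 4 members of each fixed list followed, by smallest adjusted p, those in the direction of most changed members first. For some lists but not all, members that moved against the others named from their list were added after their values were seen (COL1A1, IL6, GRWD1, CEP55, GINS3, CDKN1A, SESN1, CXCL10, VLDLR, PDIA4, HSP90AA1, KLF2, MCL1, MYOF, WIPI1 and COX6C), as was CSF1R. Any other gene is said to be chosen after its values were seen.

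Gene lists, 31 in number, were fixed before the data were examined. Those with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 28 lists. Camera with an estimated correlation and fry, both planned, were run beside it. On simulated data for this comparison with 11789 genes, 200 of them changed, the fit recovered 88% of the genes changed 1.25-fold and 100% of those changed 1.5-fold, 2-fold or 4-fold. It called 213 genes, 19 of them unchanged. The simulated noise was drawn independently for each gene and library, and far fewer genes changed than were called in the data. The simulation therefore does not show recovery or false calls under noise shared across genes, such as trends on GC content.

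Matches of all 7-mers in 3′ UTRs were scored against the fold changes of the 10771 tested genes (91.4%) with an annotated 3′ UTR of at least 50 nt, with adjustment for the GC content and length of each 3′ UTR, the expression of its gene and for the GC and CpG content of each 7-mer. Trends on GC content and transcript length were removed from each library by a loess fit (span 0.5, degree 2) over the 11579 tested genes (98.2%) with an annotated transcript. Alternatives planned before the data were examined covered scaling, the filter on low values, robust estimation, a replicate block, the set test and leaving out each replicate. Others, added after seeing the data, covered quantile normalization, the pseudocount, the variance trend, small RNAs, more scalings in the set test, GC and length trends, and genes with 3′ UTR matches. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for the other steps. Reads of near-identical copies, such as histone genes or the SLC2A3 and SLC2A14 pair, and of overlapping or antisense genes may have been split by the authors' counting, so values of such genes are uncertain.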

Results

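The transcriptome of MDA-MB-231 cells, a triple-negative breast cancer line, was measured by RNA-seq in 3 libraries from cells transfected with a negative control siRNA and 3 from cells transfected with an siRNA against NRDE2. NRDE2 is a nuclear protein that binds the RNA helicase MTREX, and the comparison asks how its loss changes the mRNA profile of these cells. Estimated depth ran from 40800000 fragments (si-NRDE2-2 replicate 3) to 56100000 (si-Control replicate 2). Values are FPKM as deposited, given as mean ± SD with n = 3 per group, and log2 fold changes of si-NRDE2-2 over si-Control are given ± SE with p-values from limma.

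Knockdown of NRDE2 was followed by small changes in many genes and large changes in few. NRDE2 mRNA was 4.39, 4.45 and 3.80 FPKM in si-Control replicates 1, 2 and 3 and 0.230, 0.234 and 0.229 FPKM in si-NRDE2-2 replicates 1, 2 and 3, so every library matched its label. The mean went from 4.21 ± 0.358 to 0.231 ± 0.00270 FPKM, a ratio of 0.0548 (log2 fold change -3.70 ± 0.10, adjusted p = 4.5e-09). The receptor tyrosine kinase gene MET rose 3.10-fold, the Notch ligand gene JAG1 2.79-fold and the cytokine gene IL1B 2.82-fold, while the RNA helicase gene MOV10 fell to 0.455 times its control level. GACGTA, GACAGTA or GACTGTA, picked from these same fold changes, lay in the 3′ UTR of 56.9% of 65 genes at least 2-fold higher. Among all genes searched the share was 17.6%. JAG1 carries GACGTA, so its rise cannot be assigned to NRDE2 loss from these data. MET, IL1B and MOV10 carry none of the 3. Only 1 NRDE2 siRNA was used, so its off-target effects on these genes were not separated from NRDE2 loss either. Lists of mesenchymal and inflammatory cytokine genes passed the set test upward and lists of sterol synthesis and ribosome biogenesis genes downward at a preset correlation between genes. With an estimated correlation 0 of them passed (adjusted p = 0.372 for mesenchymal, 0.921 for cytokine, 0.451 for sterol and 0.921 for ribosome biogenesis genes), and the cytokine list did not pass fry (adjusted p = 0.0739).

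Of 11789 genes tested, 5185 (44.0%) changed at an adjusted p under 0.05, 2469 of them higher and 2716 lower with si-NRDE2-2. Their median absolute log2 change was 0.29. A change of at least 2-fold was found for 68 genes that rose and 12 that fell, and one of at least 1.5-fold for 369 that rose and 194 that fell. The values of the groups did not overlap for 6303 tested genes (53.5%, where chance gives 10%). The first principal component held 73.2% of the variance and separated the groups. The SD over genes of the log2 difference was 0.11 to 0.17 between libraries of one group and 0.30 to 0.32 between libraries of different groups. Without si-NRDE2-2 replicate 1, 23 genes fell at least 2-fold. With GC and length trends removed from each library 6478 genes changed. With a pseudocount of 1 in place of 0.1, the log2 fold change of NRDE2 was -2.08.

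**Figure D1:**
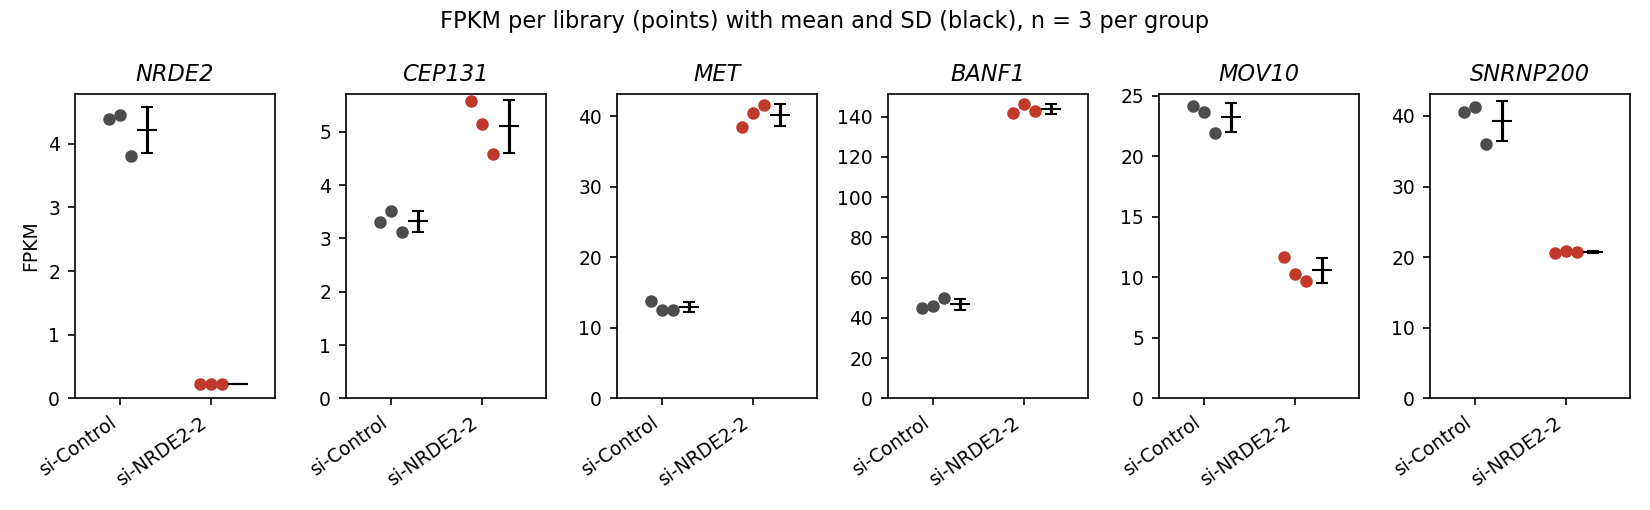
FPKM (vertical axes) of 6 genes in each library, with points for libraries and black marks for the mean with its SD (n = 3) of si-Control and of si-NRDE2-2. NRDE2 went from 4.21 to 0.231 FPKM and MET from 13.0 to 40.2 FPKM, and the libraries of the groups did not overlap in any of the 6 genes.

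CEP131, which encodes a protein of the centriolar satellites, rose from 3.32 ± 0.191 to 5.10 ± 0.494 FPKM (log2 fold change 0.60 ± 0.08, adjusted p = 1.3e-04). The 12 genes with the largest rise by the naming rule had log2 fold changes from 1.34 to 1.79. SERPINA3, an acute-phase protease inhibitor, led with 4.88 ± 1.04 to 16.8 ± 1.22 FPKM (1.79 ± 0.13, adjusted p = 4.9e-06). PTPMT1, a mitochondrial phosphatase of cardiolipin synthesis, followed at 1.75 ± 0.07. MET went from 13.0 ± 0.663 to 40.2 ± 1.56 FPKM (1.62 ± 0.05). BANF1, a chromatin-binding protein of the nuclear envelope, went from 46.8 ± 2.68 to 144 ± 2.32 FPKM (1.62 ± 0.05). The others were the vesicle fusion gene VAMP7 (1.57 ± 0.06), IL1B (1.49 ± 0.16), JAG1 (1.47 ± 0.04), the endoplasmic reticulum calcium-binding gene CALU (1.45 ± 0.05), WWTR1 (1.42 ± 0.05), which encodes the Hippo pathway coactivator also called TAZ, FAM49B (1.42 ± 0.05), the TNF family ligand gene TNFSF15 (1.39 ± 0.12) and the calcium-binding gene PDCD6 (1.34 ± 0.05). Of these 12 genes, 8 had at least 1 copy of GACGTA, GACAGTA or GACTGTA in the annotated 3′ UTR (PTPMT1, BANF1, VAMP7, JAG1, WWTR1, FAM49B, TNFSF15 and PDCD6), against 17.6% of all tested genes with a 3′ UTR. These sequences were picked from a scan of the same fold changes, so this share is not independent evidence. With all genes that carry such a sequence left out, 31 genes were at least 2-fold higher.

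The 12 genes with the largest fall had log2 fold changes from -1.32 to -0.97. The ubiquitin ligase gene TRIM6, which shares exons with a readthrough transcript into TRIM34, went from 7.61 ± 0.480 to 2.98 ± 0.181 FPKM (-1.32 ± 0.07, adjusted p = 2.0e-07). MOCOS, the molybdenum cofactor sulfurase gene, fell by 1.24 ± 0.05 on the log2 scale and was the only one with such a sequence among the 11 whose 3′ UTR was searched, the non-coding UCA1 being left out. MOV10, an RNA helicase bound to Argonaute proteins, went from 23.2 ± 1.20 to 10.6 ± 1.04 FPKM (-1.13 ± 0.07). Tafazzin, listed under its older symbol TAZ and needed for mature cardiolipin, fell from 16.1 ± 0.621 to 7.41 ± 0.601 FPKM. The long non-coding RNA UCA1 (-1.12 ± 0.07), the adhesion molecule gene MCAM (-1.07 ± 0.05), SYTL1 (-1.01 ± 0.07), the RhoGEF gene ARHGEF10 (-1.01 ± 0.07), the DNA repair helicase gene ERCC2 (-0.98 ± 0.06) and the kinase gene STK25 (-0.97 ± 0.06) were also among them. The haem synthesis gene ALAD fell to 0.494 and CNTNAP1 to 0.496 times its control level.

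**Figure D2:**
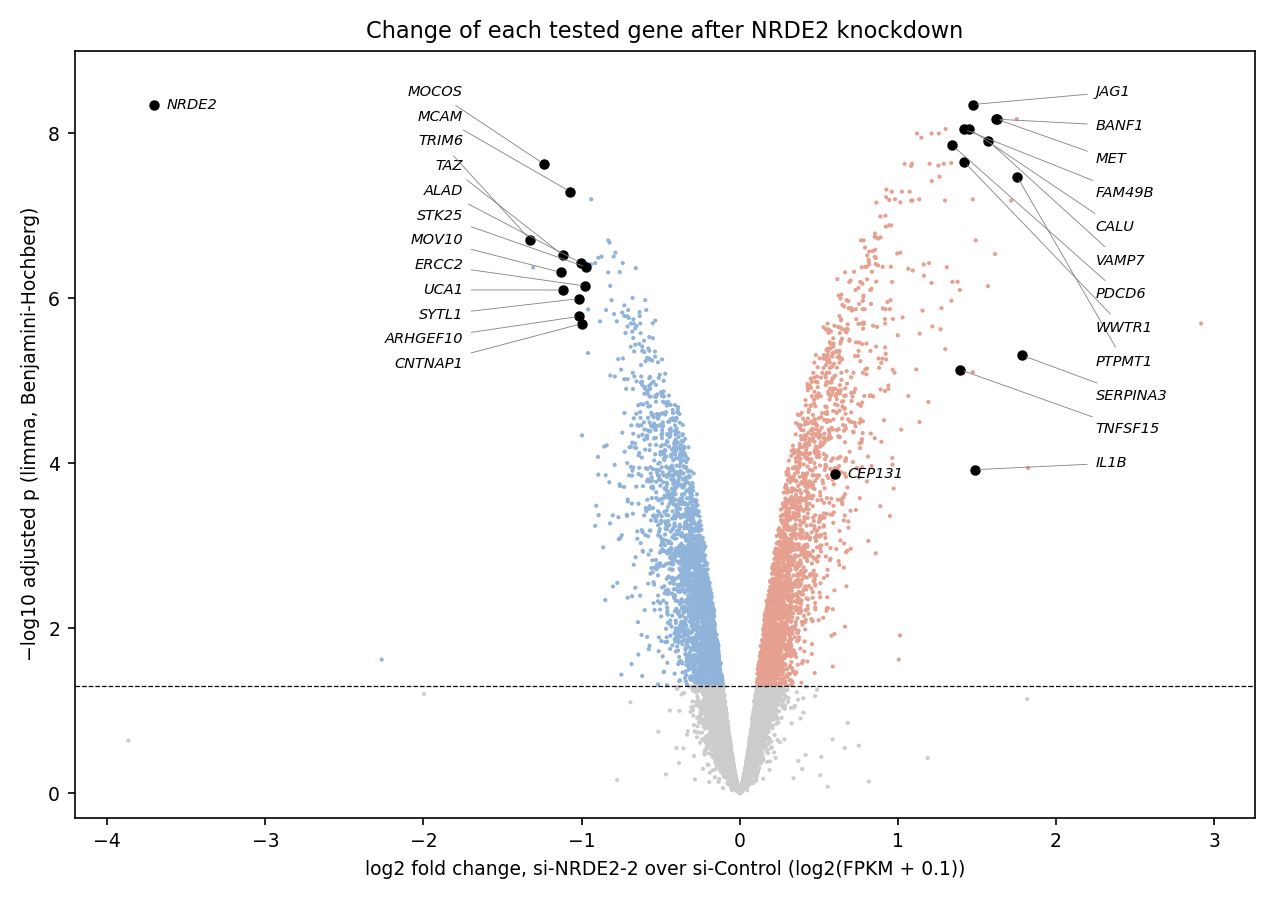
Each point is 1 of the 11789 tested genes, with the log2 fold change of si-NRDE2-2 over si-Control on the horizontal axis and the adjusted p (limma) on a -log10 scale on the vertical axis. The dashed line marks an adjusted p of 0.05, and NRDE2 lies at a log2 fold change of -3.70.

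Genes closest to NRDE2 and genes of RNA decay and splicing moved in both directions. Of 14 partners and nuclear exosome adaptors 3 rose, among them ZFC3H1 (0.29 ± 0.06) and RBM7 (0.29 ± 0.06), and 1 fell, the cap-binding gene NCBP1 (-0.50 ± 0.06). The set test gave adjusted p = 0.705, and the list's median (-0.0024) and mean (0.02) differ in sign, the test pointing up. Of 14 RNA exosome subunits and cofactors 3 rose and 2 fell (adjusted p = 0.816, median -0.00066, mean 0.05, the test pointing up). The exosome cofactor gene C1D rose from 7.61 ± 0.557 to 15.01 ± 1.85 FPKM (0.97 ± 0.09), whereas the subunit gene EXOSC5 fell by 0.34 ± 0.04. Of 32 core spliceosome genes 6 rose and 7 fell, or 6 when adjusted over the list alone. With GC and length trends removed 11 rose and 8 fell. The helicase gene SNRNP200 fell from 39.3 ± 2.80 to 20.8 ± 0.125 FPKM (-0.91 ± 0.05, adjusted p = 3.8e-07), and its U5 partner PRPF8 fell by 0.29 ± 0.05. This list's median (0.05) and mean (-0.006) differ in sign, and the set test, pointing up, gave adjusted p = 0.645. The median of the spliceosome list was 0.03 without si-Control replicate 1 and 0.03 without si-NRDE2-2 replicate 1 or 2. When single replicates were left out, the medians of the partner and exosome lists ran from -0.0075 to 0.019 and from -0.029 to 0.0086. The partner median was above 0 in each of these fits except that without si-NRDE2-2 replicate 3, and the exosome median was above 0 without si-Control replicate 2 or 3 or si-NRDE2-2 replicate 2 or 3.

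Of the 28 lists tested as sets, 12 passed camera at the preset correlation, 5 upward and 7 downward, while 0 of them passed with an estimated correlation and 8 lists passed fry. For 20 of the 30 lists with a tested member the counts of genes that rose and fell were equal when adjusted over the list alone, and the other 10 are given beside their counts. Of 31 mesenchymal genes 19 rose and 3 fell (21 and 4 adjusted over the list alone), with a median log2 change of 0.25 (adjusted p = 5.1e-05, adjusted p = 0.372 with an estimated correlation). The matrix gene FN1 rose from 67.0 ± 2.72 to 108 ± 5.92 FPKM, and COL6A1, TGFBI and the protease inhibitor gene TIMP3 rose by 0.56 ± 0.04, 0.53 ± 0.04 and 0.51 ± 0.04, whereas the collagen gene COL1A1 fell by 0.56 ± 0.09. Of 23 NF-kB and cytokine genes 14 rose and 1 fell (14 and 3 adjusted over the list alone, median 0.33, adjusted p = 0.003, adjusted p = 0.921 with an estimated correlation). By fry, this list's adjusted p was 0.0739, within a range of 1.2e-04 to 0.0739 over its alternatives other than the estimated correlation. Its median was 0.21 without si-Control replicate 2 and 0.21 with a mean FPKM of at least 5. The adhesion receptor gene ICAM1 went from 85.4 ± 9.36 to 146 ± 10.9 FPKM, the chemokine gene CXCL8 from 197 ± 30.2 to 344 ± 28.8 FPKM and CCL2 from 1.24 ± 0.109 to 2.19 ± 0.111 FPKM. The cytokine gene IL6 was the one that fell (-0.28 ± 0.10, adjusted p = 0.0344), a call lost without si-Control replicate 1 or 3 (adjusted p = 0.123 and 0.106) and without si-NRDE2-2 replicate 2 or 3 (adjusted p = 0.138 and 0.0804), and also with no filter on low values, with small RNAs kept, with no variance trend and with GC and length trends removed (adjusted p = 0.108, 0.0663, 0.0646 and 0.0549, range 0.0066 to 0.138). Without si-Control replicate 3 its log2 fold change was -0.18. Of 28 hypoxia and glycolysis genes 12 rose and 2 fell (median 0.08, adjusted p = 0.0065, adjusted p = 0.921 with an estimated correlation). Among them were the glucose transporter gene SLC2A3 (0.94 ± 0.04), whose reads may be shared with its near copy SLC2A14, CA12 (0.84 ± 0.05), EGLN3 (0.63 ± 0.05) and NDRG1 (0.57 ± 0.05). Of 10 basal and triple-negative cell markers 5 rose and 0 fell (median 0.14, adjusted p = 0.0229, adjusted p = 0.873 with an estimated correlation), among them CAV2 (0.42 ± 0.06), ANXA1 (0.34 ± 0.05) and CD44 (0.26 ± 0.04). With a mean FPKM of at least 5 this median was 0.08.

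Of 26 sterol synthesis and uptake genes 15 fell and 1 rose (median -0.24, adjusted p = 5.1e-05, adjusted p = 0.451 with an estimated correlation). The regulator SREBF2 went from 42.2 ± 0.787 to 32.2 ± 0.326 FPKM, and the enzyme genes TM7SF2, FDFT1 and DHCR7 changed by -0.58 ± 0.06, -0.41 ± 0.04 and -0.36 ± 0.04. Of 30 genes of ribosome biogenesis and MYC targets 16 fell and 3 rose (18 and 3 adjusted over the list alone, median -0.15, adjusted p = 0.0065, adjusted p = 0.921 with an estimated correlation). The pyrimidine synthesis gene CAD fell by 0.56 ± 0.06, the RNA polymerase I gene POLR1A fell by 0.49 ± 0.08, and MYC itself went from 117 ± 3.398 to 88.6 ± 3.25 FPKM, whereas the ribosome assembly gene GRWD1 rose by 0.95 ± 0.05. Of 24 snoRNA hosts and transcripts sensitive to nonsense-mediated decay 13 fell and 1 rose (median -0.18, adjusted p = 0.0033, adjusted p = 0.921 with an estimated correlation). The non-coding RNA GAS5 went from 376 ± 40.8 to 255 ± 14.6 FPKM and ZFAS1 from 282 ± 31.3 to 211 ± 5.58 FPKM, and SNHG17 and SNHG12 changed by -0.57 ± 0.05 and -0.35 ± 0.05.

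The other 5 lists past camera lost their call when single libraries were left out. Of 35 mitotic genes 14 fell and 0 rose (median -0.10, adjusted p = 0.0229, adjusted p = 0.921 with an estimated correlation), among them PLK1 (-0.37 ± 0.04), TPX2 (-0.38 ± 0.05), PRC1 (-0.35 ± 0.04) and CDC20 (-0.31 ± 0.05). Removal of GC and length trends gave 20 that fell and 3 that rose. The adjusted p of this list was 0.134 without si-NRDE2-2 replicate 1, 0.0505 without si-Control replicate 2 and 0.0628 by fry, in a range of 0.0053 to 0.134 over its alternatives other than the estimated correlation. Of 32 genes of homologous recombination and Fanconi anaemia 12 fell and 2 rose (median -0.14, adjusted p = 0.0103, adjusted p = 0.921 with an estimated correlation), with an adjusted p of 0.0590 without si-NRDE2-2 replicate 1 and 0.0628 by fry (range 0.0012 to 0.0628). In this list 18 fell and 2 rose with GC and length trends removed. FANCA fell from 9.35 ± 1.14 to 5.70 ± 0.261 FPKM, and RAD54L, FANCG and CHEK2 changed by -0.51 ± 0.08, -0.45 ± 0.04 and -0.37 ± 0.05. Of 29 centrosome and centriolar satellite genes 13 fell and 2 rose, CEP131 and CEP55 (0.26 ± 0.06) being those that rose (median -0.16, adjusted p = 0.0376, adjusted p = 0.921 with an estimated correlation). The gamma-tubulin gene TUBG1 fell by 0.44 ± 0.05, PCNT fell by 0.43 ± 0.08 and CEP164 fell by 0.31 ± 0.06. This list's adjusted p was 0.130 and 0.0668 without si-Control replicates 1 and 2, 0.113 without si-NRDE2-2 replicate 1, 0.0687 when libraries were scaled to the same FPKM total and 0.105 by fry (range 0.0044 to 0.130). Of 25 SR protein and hnRNP genes 8 rose and 1 fell (median 0.08, adjusted p = 0.0461, adjusted p = 0.921 with an estimated correlation), among them SRSF5 (0.33 ± 0.04), the splicing kinase gene CLK1 (0.23 ± 0.04) and HNRNPM (0.19 ± 0.04). Its adjusted p was 0.0556 and 0.0624 without si-Control replicates 1 and 2, and 0.0998 and 0.0976 without si-NRDE2-2 replicates 2 and 3 (range 0.0193 to 0.186). It was 0.0711 with the replicate number as a block, 0.0678 with a mean FPKM of at least 5, 0.186 with quantile normalization and 0.0905 with GC and length trends removed, where the median was 0.04 and 9 rose and 4 fell. Of 16 epithelial adhesion genes 6 fell and 1 rose (7 and 1 adjusted over the list alone, median -0.12, adjusted p = 0.0376, adjusted p = 0.921 with an estimated correlation), with the junction genes OCLN (-0.61 ± 0.06), DSP (-0.41 ± 0.06) and CLDN7 (-0.32 ± 0.06) among those that fell. Its adjusted p was 0.0505 and 0.109 without si-Control replicates 2 and 3 and 0.0551 without si-NRDE2-2 replicate 3 (range 0.0149 to 0.255), and the median was -0.08 without si-Control replicate 3. It was 0.255 with a mean FPKM of at least 5 and 0.0655 with GC and length trends removed. Without the genes that carry the 3′ UTR sequences above, the mitotic, SR protein and epithelial lists had adjusted p-values of 0.0575, 0.0575 and 0.0715. The mitotic and epithelial lists lost 0 members there and kept their medians (-0.10 and -0.12), so the change lies in the other genes and lists of the test, not in their own members. The SR protein list went to 21 members and a median of 0.07.

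**Figure D3:**
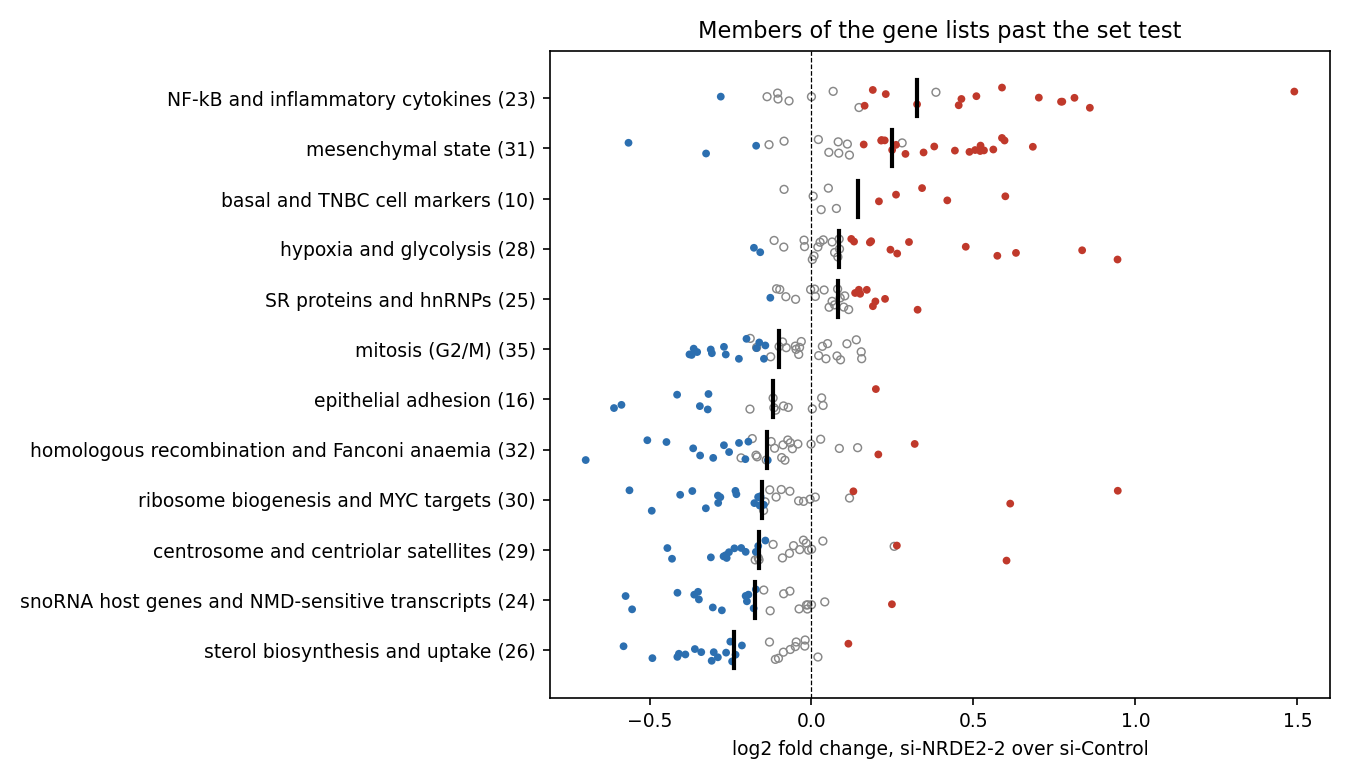
Log2 fold change (horizontal axis) of each tested member of the 12 lists past camera at the preset correlation, with the number of tested members in brackets. Filled points passed an adjusted p of 0.05 (limma), open points did not, and black bars are medians, from 0.33 for NF-kB and cytokine genes to -0.24 for sterol genes.

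The other lists did not pass camera. Of 34 DNA replication genes 7 rose and 10 fell (adjusted p = 0.997, median -0.01, mean -0.0073, the test pointing up, medians from -0.044 to 0.025 when single replicates were left out), with CDC45 at -0.54 ± 0.05, RRM2 at -0.44 ± 0.06 and GINS3 at 0.64 ± 0.09. Among 24 p53 targets 5 rose and 9 fell (adjusted p = 0.816). The cell cycle inhibitor gene CDKN1A rose from 51.2 ± 2.00 to 83.2 ± 1.21 FPKM (0.70 ± 0.04) and SESN1 rose by 0.76 ± 0.09, while the death receptor gene FAS (-0.55 ± 0.08) and GDF15 (-0.36 ± 0.09) fell. Of 30 interferon-stimulated genes 5 rose and 11 fell (12 adjusted over the list alone, adjusted p = 0.322), with IFIT1 going from 12.01 ± 0.354 to 7.56 ± 0.325 FPKM and HERC5 from 11.6 ± 0.480 to 7.78 ± 0.280 FPKM, while the chemokine gene CXCL10 rose by 0.95 ± 0.15. With GC and length trends removed 8 rose and 14 fell. Of 27 ATF4 targets 1 rose and 9 fell (adjusted p = 0.130), with DDIT3 at -0.55 ± 0.06, ATF3 at -0.41 ± 0.04 and VLDLR, the one that rose, at 0.57 ± 0.05. With libraries scaled to the same FPKM total the adjusted p of this list was 0.0409, and with quantile normalization 0.0239 (range 0.0239 to 0.397). Of 23 genes of the unfolded protein response 4 rose and 7 fell (adjusted p = 0.907, median -0.05, mean 0.02, the test pointing down, median -0.02 without si-Control replicate 2 or 3), the chaperone gene HSPA5 falling (-0.43 ± 0.06) and the protein disulfide isomerase gene PDIA4 rising (0.82 ± 0.05). In this list 7 rose and 7 fell with GC and length trends removed. Of 12 heat shock genes 2 rose and 5 fell (adjusted p = 0.383), HSPA4L falling (-0.71 ± 0.06) and HSP90AA1 rising (0.78 ± 0.05). Of 18 immediate early genes 5 rose and 8 fell (adjusted p = 0.381), with the AP-1 gene FOSL1 going from 215 ± 8.99 to 141 ± 12.7 FPKM and the phosphatase gene DUSP5 from 145 ± 7.86 to 97.6 ± 4.55 FPKM, while KLF2 rose by 1.16 ± 0.08 and MCL1 by 0.98 ± 0.04.

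Among 22 YAP/TAZ targets 6 rose and 6 fell (7 and 7 adjusted over the list alone, adjusted p = 0.705), PTPN14 rising by 0.98 ± 0.09 and CRIM1 by 0.48 ± 0.05, and MYOF falling (-0.41 ± 0.05). Removal of GC and length trends gave 9 that rose and 6 that fell. Of 29 lysosome and autophagy genes 10 rose and 3 fell (adjusted p = 0.130), including the protease gene CTSB (0.31 ± 0.05) and LAMP1 (0.27 ± 0.04), which rose, and WIPI1 (-0.57 ± 0.04), which fell. Without si-Control replicate 3 this list's adjusted p was 0.0380, with a median of 0.08 against 0.04. The median was 0.02 without si-Control replicate 1 (adjusted p = 0.204) and 0.02 without si-NRDE2-2 replicate 1 (adjusted p = 0.281). With GC and length trends removed it was 0.0469 (median 0.07, 13 rose and 4 fell), in a range of 0.0380 to 0.281. Of 35 nuclear-encoded oxidative phosphorylation genes 3 rose and 4 fell (2 and 3 adjusted over the list alone, adjusted p = 0.645), including COX5A (-0.32 ± 0.05) and COX6C (0.37 ± 0.05), and with GC and length trends removed 4 rose and 8 fell. Of 48 cytosolic ribosomal protein genes 1 rose and 7 fell (0 and 4 adjusted over the list alone, adjusted p = 0.234), including RPL7A (-0.28 ± 0.06). This list's adjusted p was 0.0086 without si-Control replicate 1 and 0.0270 with libraries scaled to the same FPKM total (range 0.0086 to 0.748). Of 13 replication-dependent histone genes, many of which have near-identical copies, 2 rose and 2 fell (0 and 2 adjusted over the list alone, adjusted p = 0.816), including HIST1H1C (-0.21 ± 0.04). The libraries were poly(A)-selected, so these values need not reflect histone mRNAs without a poly(A) tail.

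Markers of other cell types were few above the filter. Of 3 leukocyte markers CD14 (1.44 ± 0.233 to 2.32 ± 0.0716 FPKM) and CD68 (64.0 ± 2.85 to 74.7 ± 1.95 FPKM) rose, and CSF1R did not pass the test (0.17 ± 0.12). Of 2 fibroblast and endothelial markers PDGFRB rose from 1.17 ± 0.0524 to 1.504 ± 0.0942 FPKM and 1, ACTA2, fell (-0.46 ± 0.15, adjusted p = 0.0263). The call of ACTA2 was lost without si-Control replicate 1 or 3, without si-NRDE2-2 replicate 2 and with no filter on low values (adjusted p = 0.0605, 0.0948, 0.0841 and 0.0876, range 0.004 to 0.0948), and its log2 fold change was -0.27 without si-NRDE2-2 replicate 2. Of 11 luminal and hormone-receptor markers 3 rose and 3 fell (adjusted p = 0.856), with the trefoil peptide gene TFF1 going from 2.48 ± 0.385 to 6.24 ± 0.618 FPKM and the receptor gene ERBB2 from 12.8 ± 0.166 to 10.6 ± 0.395 FPKM. These marker lists, like the list of mitochondrially encoded transcripts with 0 tested genes, say nothing on genes under the filter. Of the list members named above, C1D, CLK1, SLC2A3, CA12, PTPN14, CRIM1, LAMP1, CEP55, CDKN1A, SESN1, GINS3, CXCL10, VLDLR, PDIA4, HSP90AA1, GRWD1, MCL1 and COX6C, which rose, and HERC5, HSPA4L, POLR1A and FOSL1, which fell, carry GACGTA, GACAGTA or GACTGTA in the 3′ UTR, as does NRDE2. The 3′ UTRs of COX5A and HIST1H1C and the non-coding RNAs named were not searched. COL1A1, IL6, GRWD1, CEP55, GINS3, CDKN1A, SESN1, CXCL10, VLDLR, PDIA4, HSP90AA1, KLF2, MCL1, MYOF, WIPI1, COX6C and CSF1R were named after their values were seen.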

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

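Rows of small RNAs, which were left out of the tested set, took a larger share of the FPKM sum after NRDE2 knockdown, 5.94 ± 0.14% against 5.15 ± 0.10% in si-Control (n = 3 each; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The 2 rows named MIR1244 held 2.20 ± 0.02% against 1.77 ± 0.14%, and the other 2045 rows held 3.74 ± 0.15% against 3.38 ± 0.04%. The libraries were poly(A)-selected, and the short length of such rows makes their FPKM unstable. These shares therefore cannot be read as levels of mature small RNAs, and fragments of overlapping or similar longer transcripts were not told apart from them.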

How the results depend on the processing

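Quantile normalization, the pseudocounts, the fit without a variance trend, small RNAs kept, the removal of GC and length trends, the fit without genes carrying the 3′ UTR sequences and, for lists, the median-of-ratios and upper-quartile scalings were chosen after seeing the data. NRDE2 kept its direction and call under every alternative that tested it, with a log2 fold change from -4.13 (pseudocount 0.01) to -2.08 (pseudocount 1), and from -3.77 to -3.66 when single replicates were left out. It had no value with a mean FPKM of at least 5 or without genes carrying the 3′ UTR sequences. The count of changed genes (5185) lay between 3929 and 6478. Of 170 genes looked at singly, 0 changed direction, and 14 of the 167 past the threshold lost their call under at least 1 alternative. NRDE2, CEP131 and the 24 genes of the largest changes lost 0 calls. With a mean FPKM of at least 5, which tests fewer genes, 52 genes changed at least 2-fold and 43 were higher. Without genes carrying the 3′ UTR sequences, which also tests fewer, 41 changed at least 2-fold and 31 were higher. With no filter, which tests more genes, 22 were at least 2-fold lower. Leaving out single replicates gave 11 to 23 genes at least 2-fold lower, 23 without si-NRDE2-2 replicate 1, and the cause was not tested.

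With an estimated correlation 0 lists passed the set test, and over the other alternatives 8 to 13 did. For 7 lists past the test in neither fit, the test turned direction, and the cause was not tested. Their median log2 changes in these fits were -0.011 by fry, with a mean FPKM of at least 5 and with the block, -0.019 with quantile normalization and -0.022 with GC and length trends removed for DNA replication, -0.066 for p53 targets and -0.048 for the unfolded protein response by fry, -0.055 with a mean FPKM of at least 5 and -0.00024 with quantile normalization for luminal markers, and -0.016 for YAP/TAZ targets without genes carrying the 3′ UTR sequences. When single replicates were left out, medians ranged from -0.044 to 0.025 for DNA replication, -0.060 to -0.019 for the unfolded protein response, -0.063 to 0.013 for oxidative phosphorylation, -0.099 to 0.025 for ribosomal proteins and -0.019 to 0.030 for luminal markers.

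The labels number the replicates 1 to 3 in both groups. They give no day or batch behind these numbers, so the numbers were not taken as pairs. Deviations of samples of the same number had correlations of -0.12, 0.11 and -0.12 across genes, which are not independent. Samples of unlike number ran from -0.11 to 0.17, so these correlations cannot decide on pairing. With the replicate block 4686 genes were called, 4610 of them among the 5185, and 11 lists passed. The DESeq2 test and limma-voom were planned and not run, since both need counts, and scaling to the same FPKM total and limma without robust estimation stood in for the planned library-size scaling and non-robust count test. Depth limits genes near 1 FPKM, most in si-NRDE2-2 replicate 3, estimated at 40800000 fragments.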

Other observations

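The search for 7-mers among genes at least 1.5-fold lower was chosen after part of its result had been seen, and the 3′ UTR and intron patterns had been seen before their tests with GC and length trends removed. The genes of the next 2 paragraphs were chosen after their values were seen.

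These genes were tested singly, not as groups. RBPJ, the DNA-binding partner of activated Notch, rose from 21.7 ± 0.698 to 52.0 ± 2.91 FPKM (log2 fold change 1.26 ± 0.05, limma adjusted p = 2.5e-08), and the Notch target gene HES1 from 6.55 ± 0.421 to 11.7 ± 0.0480 FPKM (0.83 ± 0.06). The receptor genes NOTCH1 (0.07 ± 0.07, adjusted p = 0.394) and NOTCH2 (-0.08 ± 0.07, adjusted p = 0.362) did not pass the test here. NOTCH1 did with GC and length trends removed (0.20, adjusted p = 0.0044, range 0.0044 to 0.838 over its alternatives), and NOTCH2 without si-Control replicate 3 (-0.16, adjusted p = 0.0243, range 0.0243 to 0.759). The syntaxin gene STX12 rose by 1.29 ± 0.05 and the endosomal GTPase gene RAB7A by 0.96 ± 0.04. The leukocyte adhesion receptor gene VCAM1 rose from 2.27 ± 0.243 to 6.54 ± 0.185 FPKM, and the tight junction gene CLDN1 rose by 1.38 ± 0.09, opposite to OCLN and CLDN7. The Ras gene NRAS and the phosphatase gene PTPN1 rose by 1.21 ± 0.05 and 1.12 ± 0.04. RBPJ, STX12, RAB7A, CLDN1, NRAS and PTPN1 carry at least 1 of the 3′ UTR sequences described below.

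Among single genes that fell, the deacetylase gene HDAC1 went from 67.0 ± 1.84 to 37.6 ± 1.30 FPKM (-0.83 ± 0.04), the acetyltransferase gene KAT2A from 20.3 ± 0.237 to 11.5 ± 0.726 FPKM (-0.82 ± 0.05), EP400 of the TIP60 complex from 7.51 ± 0.692 to 4.20 ± 0.193 FPKM (-0.82 ± 0.07) and SMARCD3 of the BAF complex from 7.33 ± 0.482 to 3.72 ± 0.193 FPKM (-0.96 ± 0.07).

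The count of 5185 changed genes was the largest of the 10 splits of the 6 libraries into 3 and 3 (1 split gave as many, the real one), and the highest of the other splits was 0 genes. Each other split mixes libraries of both groups, so a real difference between the groups adds to its spread and lowers its count. These counts therefore do not show how many genes would be called without a group difference, and no conclusion is drawn from them. The splits are also too few for a share under 0.05.

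Among 16106 7-mers, 12 in 3′ UTRs went with higher values after NRDE2 knockdown at a standard score above 4.7, led by GACAGTA (12.7, 0.15 higher on the log2 scale, 813 genes) and TGACGTA (12.2, 0.31 higher, 144 genes). GACGTA, GACAGTA and GACTGTA were picked from this scan after its result was seen, so the sizes given for them describe the pattern and do not test it. GACGTA was in the 3′ UTR of 3.82% of genes and of 32.3% of those at least 2-fold higher, and genes with it lay 0.24 higher in the median (95% bootstrap interval 0.18 to 0.29), against 0.10 with it in the coding region. The other 2 sequences went with smaller differences. For GACAGTA the shares were 7.55% and 24.6% and the difference 0.13, against 0.02 in the coding region. For GACTGTA they were 8.78% and 12.3%, with a difference of 0.08, against -0.007 in the coding region. A motif acting on either strand is argued against by the highest standard score of the 2 reverse complements, -0.160, and GC and length bias as the whole cause by a difference of 0.22 (0.18 to 0.28) after both trends were removed. A candidate explanation left open is that the control siRNA lowers these mRNAs through its seed, so that they read as higher in its absence. The labels name it as the Ambion product AM4611, but its sequence is not given in the sources used here, so both the identity of the control and its seed need checking. An effect of NRDE2 loss itself on mRNAs with such 3′ UTRs was not tested and stays open, so the rise of a gene with such a sequence cannot be assigned to NRDE2 loss from these data.

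The same scan bears on whether the NRDE2 siRNA lowers genes through its own seed, since its sequence lies in the NRDE2 mRNA. The 7-mer with the lowest fold changes, GGATTAC, had a standard score of -4.97 (0.05 lower on the log2 scale, 1453 genes). It lies in the NRDE2 mRNA, but so do 50.4% of all 7-mers scored, so for the 2716 lower genes a seed effect and an effect of NRDE2 loss cannot be told apart. GTCTCGA (-4.66) and its reverse complement TCGAGAC (-4.41) were both among the lowest 7-mers. Matches to 1 seed, which lie on 1 strand, would not give such a pair. Low scores in this scan therefore need not mark a seed, and other sources of them were not tested. Among the 169 genes at least 1.5-fold lower with a 3′ UTR, the leading 7-mer of the NRDE2 mRNA was in 11.2%, against 5.70% of all genes (smallest Bonferroni-adjusted p = 1 in an exact hypergeometric test), where the same search among genes at least 1.5-fold higher found GACAGTA in 23.9%. Unlike the scan, this search was not adjusted for the length or GC content of 3′ UTRs. Transcripts of genes at least 1.5-fold lower were richer in GC (median 54.0%, against 48.8% in all tested genes with introns). The search therefore cannot decide whether matches to 1 seed lie behind these larger falls, and no conclusion is drawn from it.

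Genes at least 1.5-fold lower had shorter introns than matched genes. They also had more introns (median 11.5, against 8 in all tested genes with introns), and intron number was not matched. Of the fifth of genes with the shortest introns 3.28% fell at least 1.5-fold, against 1.51% of the fifth with the longest. Their median intron length was 1084 bases in the median, against 1623 (1361 to 1922) in 10000 draws of genes matched on GC content, transcript length and expression (190 genes, one-sided permutation p = 1e-04, the smallest the draws can give). Libraries differed in GC trend within a group (Spearman correlation across genes, which are not independent, up to 0.668 in size), so GC and length trends were removed from each library. The gap then was 1391 against 1827 bases (1525 to 2176, 174 genes, one-sided permutation p = 0.0014), which argues against these trends as the whole cause. That poorer splicing of short introns after NRDE2 loss lowers these mRNAs is a hypothesis that was not tested. Gene-level FPKM do not separate spliced from intron-retaining transcripts for any gene, CEP131 among them. Reads over introns and splice junctions would be needed.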
